A study of Mus musculus with 6 samples.

How the data were processed

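RNA of 6 samples of mouse embryonic stem cells, 3 control and 3 Chd1 shRNA, was analysed by bead array. Per the labels' protocols, cells grew with LIF and 15% serum over embryonic fibroblasts that mitomycin C had stopped from dividing, pHYPER vectors were introduced by electroporation, RNA was purified on RNeasy columns, and biotinylated cRNA was made with a TotalPrep kit. What the control vector contains is not given in the sources used here. Samples were assigned to groups by the transfection label. Replicates were numbered in accession order, which names a sample and pairs none.

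The deposited unnormalized table gives an intensity for each of 45281 probes on each array, summarised over beads with GenomeStudio per the submitters' processing notes, whose version is not given in the sources used here. Its values are linear and not background-subtracted. Array medians were 114.1, 102.0 and 96.6 for control replicates 1, 2 and 3 and 110.3, 108.3 and 114.4 for Chd1 shRNA replicates 1, 2 and 3. The same deposited table gives a detection p-value for each probe on its array, small for probes above the negative controls, per the file headers and the values. A second deposited table holds intensities that the authors had processed. It is linear and not centred, each column ranks the probes as the unnormalized column of the same sample does (Spearman rho of 1), and column medians lie between 107.604 and 107.631, as after quantile normalization. The method behind it is not given in the sources used here. That table was used only as an alternative. All columns of values were matched to a sample by their names.

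Background was corrected by normal-exponential convolution with the negative-control mean and variance inferred from the detection p-values and an offset of 16, followed by quantile normalization and a log2 transform (the neqc steps of limma 3.58.1 in R 4.3.3). An offset and quantile normalization shrink differences of dim probes and remove any shift of the whole distribution between arrays. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept, 16018 in all. GEO's platform annotation listed 1 gene for 34885 probes, several genes for 18 and none for 10378, which stay unnamed here. Symbols were checked through gene identifiers against a RefSeq table of GRCm38, which changed 0 of them. Each gene was represented by its probe with the highest mean over the 6 arrays, whatever its other probes showed, and unnamed probes stood for themselves, giving 9507 named genes and 2093 unnamed probes. A gene with a probe detected on no array of a group has only a bound there, the bright group's mean over the higher of the dim probe's signal and the lowest detected signal of each array.

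Differences (Chd1 shRNA minus control) were fitted with lmFit and tested with eBayes in limma, with Benjamini-Hochberg adjustment over all 11600 genes tested and a threshold of 0.05. All SEs and adjusted p-values of single genes come from this fit, except that the 4 Chd1 probes were also tested in a fit of every kept probe. For probes other than ILMN_1258834 the values are from that fit. The number of detected probes and each Chd1 probe were also compared by an exact two-sided permutation test.

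Before the data were examined, 28 gene lists were written from textbook knowledge: pluripotency, formative and primed pluripotency, neural, mesoderm, endoderm, trophectoderm, fibroblast feeder, interferon-stimulated, p53 target, integrated stress response, heat shock, ribosomal protein, ribosome biogenesis, histone, DNA replication, mitosis, chromatin remodeller, transcription elongation, Hox, 2-cell-like, germline, imprinted, sterol synthesis, glycolysis and hypoxia, respiration, FGF and ERK, BMP and TGF-beta, and LIF and WNT target genes. Lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. A list's score on an array is the median over members of the log2 intensity minus the gene's 6-array mean. The fibroblast score used as a covariate is the mean log2 intensity of the 19 tested fibroblast genes. A second list of fibroblast genes and a short list of blood, heart and other organ genes were written after the scores of the first fibroblast list had been seen and before their own values were. Of these lists, 27 of 42 and 4 of 25 genes were tested.

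Named genes followed a rule set before the data were examined. Chd1 is named, and since no gene passed the threshold, the 6 genes with the smallest p in each direction are given as values, without clone-style names. From each list the 2 members with the largest absolute change are given as values. Genes named outside this rule are said to have been chosen after their values were seen.

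Each alternative was tried on its own: an offset of 50, no background correction (values under 1 set to 1), median scaling, the authors' processed table on a log2 scale (values under 16 set to 16), no detection filter, a stricter filter (detection p under 0.01 on all 6 arrays), every probe tested, an intensity trend with robust variance, array weights, and each of the 6 arrays left out. Scaling to the 75th percentile, the fibroblast score as a covariate, and the replicate number in accession order as a block, a pairing that the labels do not give, were added after seeing the data.

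The fits were tested on simulated data for this comparison, with the means and residual SDs of the 11600 genes and 200 genes changed by known folds in each of 20 simulations. The share of changed genes recovered at an adjusted p under 0.05 was 2.6% at 1.5-fold, 38.7% at 2-fold, 75.4% at 3-fold and 81.7% at 4-fold, with a mean of 3.6 false calls. A pluripotency list shifted by -0.5 was called in 20 of 20 simulations at the preset correlation and in 15 with an estimated one, and a mean of 0.05 of the 28 lists was called with no shift. When the arrays also carried a shared random score along the fitted differences, unrelated to group, a mean of 1.15 lists was called at the preset correlation and 0 with an estimated one. Apart from that score, simulated genes were drawn independently. In the real arrays the estimated inter-gene correlation ran from -0.06 in the neural list to 0.92 in the 2-cell-like list. The simulated recovery and false-call counts therefore need not carry over to the real arrays. Figures were drawn with matplotlib 3.10.9 in Python.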

Results

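Gene expression was measured in mouse embryonic stem cells that had been electroporated with a short hairpin RNA (shRNA) vector against Chd1 or with a control vector. Chd1 encodes an ATP-dependent chromatin remodeller that binds methylated histone tails at active genes. Total RNA of 3 control samples and 3 Chd1 shRNA samples was labelled and hybridised to 1 Illumina BeadChip, 1 array per sample. The cells had grown on inactivated embryonic fibroblast feeders with leukemia inhibitory factor (LIF) and serum, and puromycin was applied for 48 h, starting 24 h after electroporation. Each array gave an intensity and a detection p-value for 45281 probes. The control arrays detected 15833 ± 147.4 probes (mean ± SD, n = 3) and the Chd1 shRNA arrays 16831 ± 553 (n = 3). Every Chd1 shRNA array detected more probes than every control array, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. The number of arrays limits the precision of all values. Replicates of a group correlated across genes at a mean Pearson r of 0.975 for control and 0.979 for Chd1 shRNA, against 0.972 between groups, and genes are not independent replicates. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples only, which may be technical. The 3 control arrays and the 3 Chd1 shRNA arrays lay in separate blocks of neighbouring positions on the chip, so position and group cannot be told apart.

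The first question was whether the targeted transcript was lower in the samples labelled Chd1 shRNA. Of 4 Chd1 probes past the detection filter, 3 were lower on every Chd1 shRNA array than on every control array. The platform annotation ties ILMN_1246790 and ILMN_2958382 to the Chd1 reference mRNA and ILMN_1258834 and ILMN_1254296 to cDNA clones of the gene, and which transcripts each probe reads was not analysed here. Probe ILMN_1258834, which represents the gene in the tests, had a normalized log2 intensity of 7.80 ± 0.96 (SD, n = 3) in control and 5.73 ± 0.39 (n = 3) in Chd1 shRNA arrays, a level of 23.7% of control. Its log2 fold change was -2.07 (SE 0.43), with an adjusted p of 0.196 by limma, so it did not pass the threshold of 0.05. Probe ILMN_1254296 gave a log2 fold change of -1.92, and probe ILMN_1246790 gave -1.15 (SE 0.19), a level of 45.1% of control. For each of these 3 probes the exact two-sided permutation p was 0.1, the smallest possible. Probe ILMN_2958382 lay near background, at 5.05 ± 0.375 in control and 4.94 ± 0.18 in Chd1 shRNA arrays (n = 3 each), a level of 92.6% of control. Its log2 fold change of -0.11 turned to 0.02 with median scaling and to 0.10 without control replicate 3. Control replicate 3 had the lowest Chd1 signal of the controls on 3 probes, 6.91 against 7.70 and 8.81 on ILMN_1258834, 6.08 against 7.02 and 7.86 on ILMN_1254296, and 6.44 beside a control mean of 6.49 on ILMN_1246790. On ILMN_2958382 it had the highest, 5.47 against 4.74 and 4.96. With array weights, ILMN_1254296 and ILMN_1246790 passed the threshold, both at an adjusted p of 0.0484 by limma. Those weights, estimated from the same arrays, were lowest for control replicate 3 (0.57) and Chd1 shRNA replicate 1 (0.61). The highest was that of Chd1 shRNA replicate 2 (2.25). All calls with array weights, of genes and of lists, thus lean least on control replicate 3 and Chd1 shRNA replicate 1. Over the alternatives that take the arrays as unpaired, the log2 fold change of ILMN_1258834 ran from -2.52 to -1.18, with adjusted p from 0.0556 to 0.625. It passed (adjusted p = 0.0169) only with the accession order taken as a pairing, which the labels do not give. With that pairing ILMN_1254296 (adjusted p = 0.0235) and ILMN_1246790 (0.0278) passed too.

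**Figure D1:**
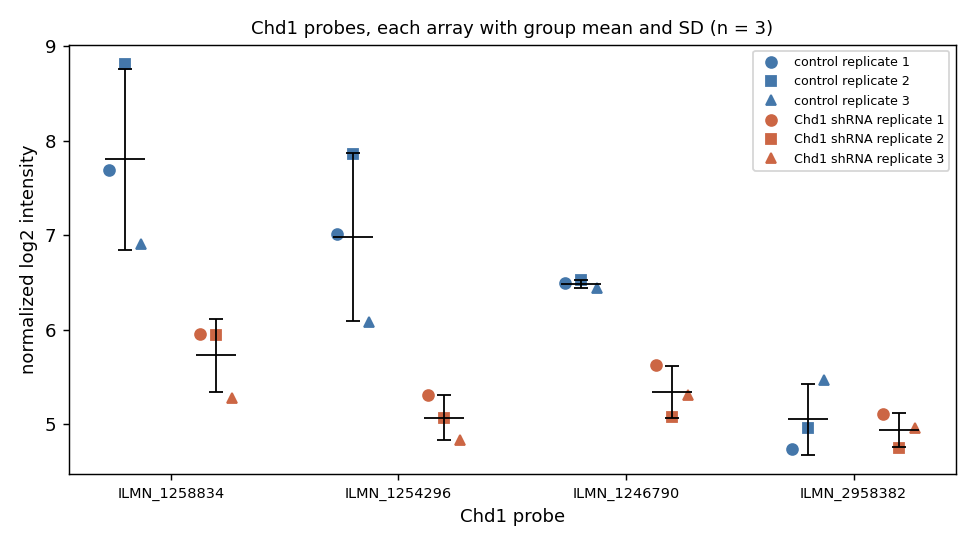
Normalized log2 intensity (vertical axis) of the 4 Chd1 probes (horizontal axis) on each of 3 control arrays (blue) and 3 Chd1 shRNA arrays (orange), with the group mean and SD as black bars. On 3 probes all Chd1 shRNA arrays lie below all control arrays, and on ILMN_2958382 the groups overlap.

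The second question was which other genes differed between Chd1 shRNA and control samples. The smallest p-values belonged to genes with lower signal in the Chd1 shRNA arrays. Aldh3a1, an aldehyde dehydrogenase, had a log2 fold change of -1.79 (SE 0.19, n = 3 per group), Krt17, a type I keratin, -1.67, and Dnajc6, which encodes the clathrin uncoating factor auxilin, -1.61. Values for Spink1, a secreted trypsin inhibitor, Notum, a carboxylesterase that inactivates WNT proteins, and Dcp2, the mRNA decapping enzyme, were -1.60, -1.50 and -1.39. In the other direction, the smallest p-values belonged to Cyp7b1, an oxysterol hydroxylase, with a log2 fold change of 1.11 (SE 0.21), Zfand3 with 1.00, Trim11, a RING-type ubiquitin ligase, with 0.97, Lrrc51 with 0.93, Arf2, a small GTPase of vesicle transport, with 0.89, and Rsad1 with 0.83. Trim11 was not detected on any control array and was at least 1.60-fold higher in Chd1 shRNA arrays. For all of these 12 genes the 2 groups did not overlap, which the choice by smallest p favours.

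None of the 11600 genes tested by limma passed an adjusted p of 0.05, and the smallest adjusted p was 0.0844, for Aldh3a1. At an unadjusted p under 0.05 there were 1268 genes, 534 higher and 734 lower in Chd1 shRNA arrays, where 580 would be reached with no difference. Of these, 39 were at least 2-fold higher and 90 at least 2-fold lower. The groups did not overlap for 1862 genes, 16.1% of those tested, where chance gives 10%. The count past the threshold was 18 with an intensity trend and robust variance, 37 with array weights, 2 with median scaling and 1 with 75th percentile scaling. It was 184, 63 higher and 121 lower, with the accession order taken as a pairing, which the labels do not give. The unadjusted count was 2052 without control replicate 3, 1952 without Chd1 shRNA replicate 1, 817 without Chd1 shRNA replicate 3 and 699 without Chd1 shRNA replicate 2, while median scaling, which moved the median log2 fold change of all genes to 0.21, put 91.0% of unadjusted calls on the higher side, against 42.1%.

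**Figure D2:**
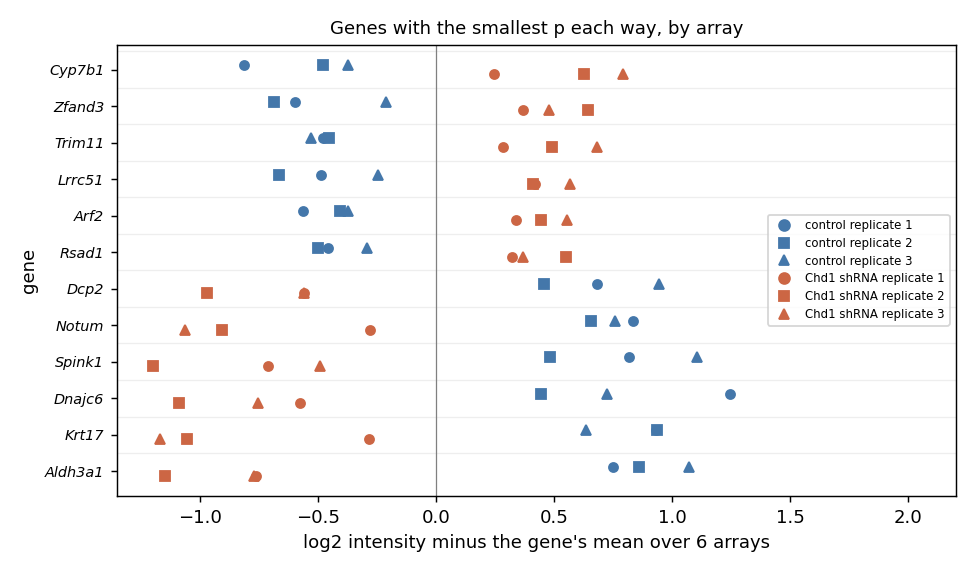
Normalized log2 intensity minus the gene's mean over 6 arrays (horizontal axis) for the 6 genes with the smallest p in each direction (vertical axis), 1 point per array, 3 control arrays in blue and 3 Chd1 shRNA arrays in orange. The groups do not overlap for any of the 12 genes, which the choice by smallest p favours. Log2 fold changes run from -1.79 for Aldh3a1 to 1.11 for Cyp7b1.

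Gene lists fixed before the data were examined asked which gene groups moved together. In the camera test with a preset inter-gene correlation of 0.01, 8 of the 28 lists passed an adjusted p of 0.05. No list passed with an estimated correlation or by fry. The estimated correlation was 0.82 in the fibroblast list and 0.10 (p53 targets) to 0.44 (DNA replication) in the other called lists. At the preset value, members count as more independent than these estimates make them, so the preset p-values overstate the evidence. Fibroblast markers were higher in Chd1 shRNA arrays as a group: 18 of 19 tested members had positive values, with a median log2 fold change of 0.83 (adjusted p = 6.81e-06; adjusted p = 0.760 with an estimated correlation). The extracellular matrix genes Dcn and Lox had values of 1.45 (SE 0.50) and 1.30 (SE 0.53). Targets of the tumour suppressor p53 were also higher as a group, 15 of 17 with a median of 0.56 (adjusted p = 0.00103; adjusted p = 0.760 with an estimated correlation), among them the death receptor gene Fas with 1.30 (SE 0.49) and the cyclin-dependent kinase inhibitor gene Cdkn1a with 1.25 (SE 0.55). Hox genes, which pattern the body axis, were higher in 16 of 19 with a median of 0.60 (adjusted p = 0.0017; adjusted p = 0.760 with an estimated correlation). Hoxc6 had a value of 1.31 (SE 0.47) and Hoxa5 1.21 (SE 0.69). No single member of these 3 lists passed over all genes tested or adjusted over the list alone. The arrays of a group differed in fibroblast signal: the median over members relative to the 6-array mean was -0.73, -0.83 and 0.36 in control replicates 1, 2 and 3, and -0.42, 0.57 and 0.87 in Chd1 shRNA replicates 1, 2 and 3. The p53 list read -0.40, -0.34 and 0.11 in control and -0.05, 0.36 and 0.45 in Chd1 shRNA arrays, and the Hox list -0.64, -0.30 and 0.09 against -0.14, 0.59 and 0.42. With the array's fibroblast score in the model, a fit chosen after seeing the data, the median was 0.17 for the p53 list and 0.20 for the Hox list, neither past the threshold, and Hoxa5 turned to -0.16. Under the other alternatives that keep the preset correlation these 3 lists stayed past the threshold, with medians from 0.12 (no detection filter) to 0.86 (stricter filter) for Hox and up to 0.86 (median scaling) for p53 targets. Left-out arrays moved the fibroblast median to 0.53 (Chd1 shRNA replicate 3), 1.25 (Chd1 shRNA replicate 1) or 1.28 (control replicate 3), the p53 median to 0.31 (control replicate 2) and the Hox median to 0.37 (control replicate 1).

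Genes of the pluripotency network were lower in Chd1 shRNA arrays as a group, with negative values for 21 of 25 members and a median log2 fold change of -0.38 (adjusted p = 0.0017; adjusted p = 0.760 with an estimated correlation). Tcl1, a cofactor of the kinase AKT, had a value of -1.19 (SE 0.24) and was the only member to pass adjusted over the list alone, where none passed over all genes. By limma over all genes, Tcl1 passed with array weights (adjusted p = 0.0481) and with the accession order taken as a pairing (0.0361), which the labels do not give. The nuclear receptor gene Nr5a2 had a value of -1.01 (SE 0.34) and passed over all genes only with that pairing (adjusted p = 0.0470). DNA replication genes were lower in 22 of 23 with a median of -0.24 (adjusted p = 0.0036; 0.760 with an estimated correlation), Gins1 with a value of -0.68 and Mcm3, a subunit of the replicative helicase, with -0.66. Mitosis genes had negative values in 11 of 14 with a median of -0.25 (adjusted p = 0.0249; 0.760 with an estimated correlation), Nusap1 with -0.48 and the spindle kinesin gene Kif11 with -0.44. Sterol synthesis genes had negative values in 12 of 14 with a median of -0.37 (adjusted p = 0.0249; 0.760 with an estimated correlation), including Dhcr7 with -0.56 and Srebf2 with -0.55. Ribosome biogenesis genes had negative values in 18 of 24 with a median of -0.20 (adjusted p = 0.0352; 0.760 with an estimated correlation), Ddx21 with -0.97 and Polr1c, a subunit shared by RNA polymerases I and III, with -0.55. In the last 4 lists no member passed over all genes or adjusted over the list alone. The pluripotency list read 0.26, 0.12 and 0.05 in control replicates 1, 2 and 3 and 0.20, -0.39 and -0.25 in Chd1 shRNA replicates 1, 2 and 3. With the fibroblast score in the model, none of these 5 lists passed, with medians of -0.15 for pluripotency, -0.01 for DNA replication, -0.11 for mitosis, -0.06 for sterol synthesis and -0.09 for ribosome biogenesis. Mitosis lost its call without control replicate 1 or 2 or Chd1 shRNA replicate 2 or 3 (medians from -0.25 to -0.18), sterol synthesis without control replicate 1 (-0.12) or Chd1 shRNA replicate 3 (-0.27), and ribosome biogenesis without control replicate 2 (-0.14) or Chd1 shRNA replicate 2 (-0.17) or 3 (-0.15). These 3 lists also lost their calls under median scaling (medians of -0.05 for mitosis and -0.13 for sterol synthesis) and under 75th percentile scaling (-0.25, -0.34 and -0.17 for ribosome biogenesis), sterol synthesis with no detection filter (-0.26), and ribosome biogenesis with the stricter filter (-0.20). Median scaling turned the ribosome biogenesis median to 0.03, where the test against other genes kept its direction, and moved those of DNA replication and pluripotency to -0.0046 and -0.19, still past the threshold.

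**Figure D3:**
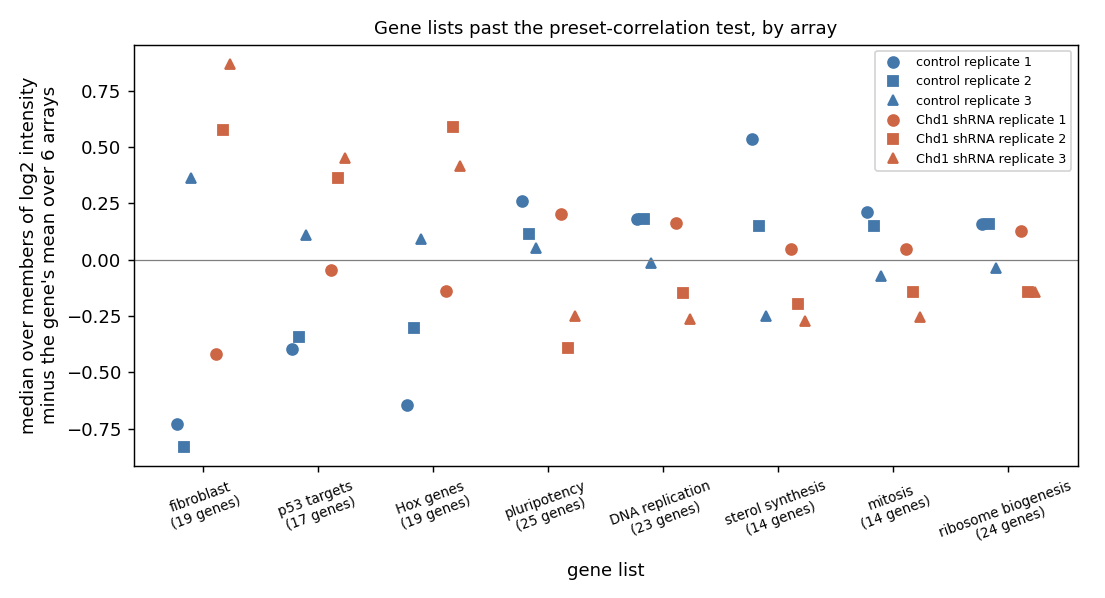
Median over a list's members of log2 intensity minus each gene's mean over 6 arrays (vertical axis) for the 8 lists past the preset-correlation test (horizontal axis, with the number of genes tested), 1 point per array, control in blue and Chd1 shRNA in orange. In the fibroblast list control replicate 3 (0.36) lies above Chd1 shRNA replicate 1 (-0.42), and the pluripotency list is lowest in Chd1 shRNA replicates 2 (-0.39) and 3 (-0.25).

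The other 20 lists did not pass. Among heat shock genes (adjusted p = 0.110, median log2 fold change 0.08), the inducible HSP70 genes Hspa1a (1.76, SE 0.41) and Hspa1b (1.06, SE 0.29) and the cochaperone gene Dnajb1 (0.70) passed adjusted over the list alone and not over all genes, Hspa1b and Dnajb1 being named after their values were seen. By limma over all genes, Hspa1a passed with median scaling (2.06, adjusted p = 0.0236). With the accession order taken as a pairing, which the labels do not give, Hspa1a (adjusted p = 0.0140) and Hspa1b (0.0317) passed. Of the differentiation lists, the mesoderm list (adjusted p = 0.521, median 0.24) held Bmp4 with a value of -1.04 (SE 0.26) and Foxc1 with 1.04, and the endoderm list (0.975, median 0.03) held Lama1, a laminin chain of basement membranes, with -1.37 (SE 0.25) and Amn with -0.85. Bmp4, Lama1 and Amn passed adjusted over the list alone. The neural list (adjusted p = 0.466, median 0.01) held Sox21 with -1.16 and Nes with 0.65, the trophectoderm list (0.541, median 0.09) Prl2c2 with 1.16 and Gata3 with 0.56, and the list of formative and primed pluripotency (0.395, median -0.34) Otx2 with -0.91 and Sox4 with 0.67. In signalling lists, Sp5, a direct target of canonical WNT signalling, had a value of 1.27 (SE 0.27) and passed adjusted over its list alone, beside Socs2 with -0.81 (LIF and WNT targets, adjusted p = 0.719, median 0.17). The list of FGF and ERK targets (adjusted p = 0.683, median -0.08) held Spry4 with -0.96 and Jun with 0.89, and the list of BMP and TGF-beta targets (0.385, median 0.08) held Id3 with 0.67 and Smad6 with 0.65. Imprinted genes (adjusted p = 0.719, median 0.01) moved both ways, with Igf2 at 1.12 (SE 0.58) and Phlda2 at -0.87 (SE 0.24). In that list Zdbf2 (-0.86), Dlk1 (0.76) and Phlda2 passed adjusted over the list alone, Zdbf2 and Dlk1 being named after their values were seen.

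For the integrated stress response list (adjusted p = 0.151, median 0.26) Ddit3 had a value of 1.34 (SE 0.77) and Slc7a3, a cationic amino acid transporter gene, -1.08 (SE 0.20), which passed adjusted over the list alone. Interferon-stimulated genes, which double-stranded RNA can induce, had a median of 0.16 (adjusted p = 0.472), with Ifitm1 at -0.99 and Usp18 at 0.60. Other chromatin remodeller genes (adjusted p = 0.385, median -0.09) included Smarcad1 with -0.67 and Smarca1 with -0.52. The transcription elongation list also held histone modification and histone chaperone genes (adjusted p = 0.472, median -0.07). It included Ccnt1 with -0.55 and Hira, a histone chaperone gene, with 0.53. The list of 2-cell-like genes (adjusted p = 0.110, median 0.38) held Tdpoz4 with 0.65 and Zfp352 with 0.58, and the germline list (0.303, median 0.14) Taf7l with 1.00 (SE 0.28) and Tex19.1 with 0.83. Histone genes (adjusted p = 0.303, median -0.06) included H2bc4 with 1.21 and H2ac18 with 0.98. Glycolysis and hypoxia genes (adjusted p = 0.181, median -0.27) included Pfkp with -0.85 and Vegfa with 0.66, respiration genes (0.683, median -0.01) Atp5a1 with -0.45 and Ndufb9 with -0.24, and ribosomal protein genes (0.719, median 0.02) Rps3a1 with -0.45 and Rpl30 with -0.38. The median and the direction of the test differed in sign for the histone, neural and endoderm lists. With the fibroblast score in the model the values of Otx2 (0.62), Igf2 (-0.011), Usp18 (-1.02) and Ndufb9 (0.03) turned.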

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

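Scaling to the 75th percentile, the fibroblast score as a covariate and a replicate block by accession order were tried only after the data had been seen. The count of genes past an adjusted p of 0.05, 0 in the limma fit as reported, was 2 with median scaling, 18 with an intensity trend and robust variance, 37 with array weights and 1 with 75th percentile scaling. It was 184 with the replicate block and 0 under every other alternative, each array left out included. The count at an unadjusted p under 0.05 (1268) was 2320 with no detection filter, where 29453 genes were tested, and 2572 with array weights, and ran from 699 (without Chd1 shRNA replicate 2) to 2052 (without control replicate 3), with 1952 without Chd1 shRNA replicate 1 and 817 without Chd1 shRNA replicate 3. Calls on the higher side were 42.1% as reported, 91.0% with median scaling and 51.8% with 75th percentile scaling. They were 50.4% with array weights, 53.4% with the replicate block and 49.1% with the covariate. Without control replicate 3 they were 51.3%, and without Chd1 shRNA replicate 1 49.1%. Every other alternative gave 36.1% to 45.2%. The count of gene lists called, 8 as reported, was 5 with median scaling, 5 with 75th percentile scaling, 2 (the 2-cell-like and germline lists) with the covariate, 0 with an estimated correlation and 0 by fry, and 6 to 10 with 1 array left out. Chd1 (probe ILMN_1258834) stayed lower and short of the threshold under the 17 alternatives without the block, between -2.52 and -1.18. Where signal is close to background, as for probe ILMN_2958382, the offset compresses fold changes.

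With the covariate, the log2 fold change turned for Hoxa5 (-0.16), Igf2 (-0.011), Ndufb9 (0.030), Otx2 (0.62) and Usp18 (-1.02), and the fibroblast list's median became -0.021, which the covariate's construction fixes near 0. Chd1 probe ILMN_2958382 turned with median scaling (0.020) and without control replicate 3 (-0.27 to 0.10 with 1 array left out), and Ndufb9 without control replicate 1 (-0.55 to 0.068). Of other values of named genes under alternatives, 1155 kept their direction and side of the threshold and 51 passed it in the same direction.

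The labels give no pairing, and replicate numbers follow the accession order and the order within each group's block of chip positions. Deviations from the group means still correlated across genes between same-numbered arrays (r of 0.38, 0.16 and 0.54 for numbers 1, 2 and 3), although control replicate 2 correlated better with Chd1 shRNA replicate 1 (0.26). With the number as a replicate block, 184 genes passed (63 higher), 2238 had an unadjusted p under 0.05, 11 gene lists passed at the preset correlation and 0 with an estimated one, and Chd1 passed with its value of -2.07 unmoved (adjusted p = 0.0169, where other alternatives gave 0.0556 to 0.625). The 5 other ways of pairing the arrays gave 0 genes each and 756 to 1885 at an unadjusted p under 0.05. The first principal component rose with the number in both groups, so the block can absorb that axis without any pairing. Pairing, that axis and order within the blocks of chip positions cannot be told apart here.

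The direction of the list test turned in 36 of 559 list values under alternatives, 1 of them in a called list, the fibroblast list. The sign of the median turned in 56, 2 of them in called lists. The medians where the test turned were, with the covariate, -0.0064 for the stress response, 0.022 for formative pluripotency, 0.020 for imprinted genes, -0.20 for interferon, -0.0054 for respiration, 0.025 for ribosomal proteins, 0.028 for elongation and 0.057 for trophectoderm. Endoderm turned with median scaling (0.23), every probe (0.076), array weights (0.053) and 75th percentile scaling (0.019), and with the replicate block (0.033), ribosomal proteins with median scaling (0.15) and 75th percentile scaling (-0.062), interferon with the stricter filter and with every probe (-0.015 each), imprinted genes (-0.048) and trophectoderm (-0.048) with no filter, LIF and WNT targets with the stricter filter (-0.24), mesoderm with every probe (0.13) and FGF and ERK targets with array weights (-0.051). Other turns came with 1 array left out, where medians ran from -0.091 to 0.16 for endoderm, -0.24 to 0.029 for FGF and ERK targets, -0.067 to 0.30 for germline, -0.17 to 0.098 for histones, -0.024 to 0.14 for imprinted genes, -0.089 to 0.26 for interferon, 0.017 to 0.18 for LIF and WNT targets, -0.068 to 0.017 for respiration and 0.0051 to 0.032 for ribosomal proteins. The cause of the turns was not tested. Lists not called as reported passed 16 times over the alternatives: the stress response with array weights (adjusted p = 0.0400) and the block (0.0409) and without control replicate 3 (0.0449) or Chd1 shRNA replicate 1 (0.0114), heat shock with no filter (0.0462) and the block (0.0349) and without Chd1 shRNA replicate 2 (0.0423), the 2-cell-like list with the covariate and the block (0.0170) and without control replicate 2 or Chd1 shRNA replicate 3, germline with the covariate and without control replicate 2 (0.0370), FGF and ERK targets (0.0370) and histones (0.0370) without control replicate 2, and glycolysis and hypoxia with every probe (0.0351).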

Other observations

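Of the tests of explanations in this part, only that of the second fibroblast gene list was fixed before its result was seen, and the others, with their bounds, were chosen afterwards, as was the fit with the fibroblast score. A set of 17 genes, 15 of them named, passed an adjusted p of 0.05 in limma both with array weights and with an intensity trend and robust variance. They are given here because of those calls, after their values were seen. All 17 had lower signal in the Chd1 shRNA arrays, with groups that did not overlap, and a median log2 fold change of -1.38. The choice by these calls favours large changes and groups that do not overlap, so neither adds support. Beside Aldh3a1, Krt17, Dnajc6, Spink1, Notum, Dcp2, Lama1 and Slc7a3, they include Mobp (-1.62), Sh3gl2 (-1.33), Lrrc34 (-1.30), the peptidase gene Dpp4 (-1.30), the kinase subunit gene Camk2b (-1.24), the keratin gene Krt42 (-1.18) and the alcohol dehydrogenase gene Adh5 (-1.09). With the array's fibroblast score in the model all 17 kept their sign, with a median of -1.26, while no gene passed the threshold in that fit. Their slopes on the score ran from -0.49 for Krt17 to 0.20 for Spink1. Genes chosen for large changes tend to keep their sign, so this adds no support either.

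The genes of the 2-cell-like state, a rare state of embryonic stem cell cultures, differed between arrays of a group. Zscan4c, named after its values were seen, read 13.02, 13.58 and 12.36 in control replicates 1, 2 and 3 and 13.63, 13.63 and 13.14 in Chd1 shRNA replicates 1, 2 and 3. With the fibroblast score in the model the list's median log2 fold change was 0.84 (adjusted p = 0.000283 at the preset correlation; adjusted p = 0.994 with an estimated correlation), and that of the germline list 0.49 (adjusted p = 0.000532; adjusted p = 0.974 with an estimated correlation). Without the score, the 2-cell-like list passed at the preset correlation without control replicate 2 (median 0.77) and without Chd1 shRNA replicate 3 (0.60), while its median was 0.07 without control replicate 3 (adjusted p = 0.889) and 0.26 without Chd1 shRNA replicate 2 (adjusted p = 0.50). With same-numbered arrays as a block it passed at the preset correlation (adjusted p = 0.0170) and not with an estimated correlation (adjusted p = 0.687), and its score differed by 0.50, 0.09 and 0.53 between those arrays.

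Beside the higher fibroblast, Hox and p53 target lists of the Chd1 shRNA arrays, the fibroblast score ranged by 1.22 and 1.21 log2 units within the groups, each more than the difference of 0.80 between the group means, so an effect of the Chd1 shRNA on the fibroblast list cannot be told apart from this spread with 3 arrays per group taken as unpaired. Between same-numbered arrays, a pairing that the labels do not give, the score differed by 0.39, 1.51 and 0.50, and with these pairs as a block the list passed at the preset correlation (adjusted p = 4.54e-10) and not with an estimated correlation (adjusted p = 0.686). Varying amounts of RNA from fibroblasts or fibroblast-like cells may account for part of the pattern. A second list of fibroblast genes, none of its 27 tested members in another list, followed the score within groups with a median slope of 1.06 (quartiles 0.71 and 1.34). Bgn and Emp1 (mean log2 intensities 11.4 and 11.3, named after their values were seen) had slopes of 1.60 and 1.06. The median slope of all genes tested was -0.04 (quartiles -0.22 and 0.16). The 4 tested blood, heart and other organ genes had a median of -0.45, below that lower quartile, so they are no neutral comparison. The Hox list had a median slope of 0.48 (quartiles 0.0085 and 0.88, positive for 15 of 19 genes). That of the p53 list was 0.33 (0.02 and 0.95, 13 of 17). Such slopes were not particular to them, as the interferon list had 0.34 (13 of 17) and the stress response list 0.25 (20 of 22). The Hox and p53 lists may read the same cells in part, but a slope cannot tell this from genes that vary together otherwise. The difference of these slopes from that of the second list was not tested. Whether such RNA came from feeder cells, from stem cells that had differentiated or from another source, and whether Chd1 shRNA raised its share, stays open. The puromycin step may have removed feeder cells unless they carried resistance, which was not measured here.

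The pluripotency list was lower in the Chd1 shRNA arrays, and dilution of stem cell RNA by other cells is a candidate explanation. With the fibroblast score in the model the list's median log2 fold change moved from -0.38 to -0.15, with quartiles of -0.50 and 0.20, so dilution and an effect of Chd1 shRNA on these genes cannot be told apart with 6 arrays. Without the score, members ranged from -1.19 for Tcl1 to 0.48 for Dppa2, while Nanog, named like Dppa2 after its value was seen, stood at 0.17.

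Control replicate 3 lay with Chd1 shRNA replicates 2 and 3 on the first principal component (50.5% of the variance), at 12.1, beside 22.5 and 35.2, with Chd1 shRNA replicate 1 at -9.70 and the other controls at -33.1 and -26.9. A swap of labels between control replicate 3 and Chd1 shRNA replicate 1 is argued against by Chd1 itself, which was higher in control replicate 3 by a mean of 0.72 log2 units over all 4 probes past the filter (0.35 to 0.95). The lowest difference was that of ILMN_2958382, near background and with overlapping groups, which cannot bear on a swap. The argument rests on ILMN_1258834 (6.91 against 5.955), ILMN_1254296 (6.08 against 5.31) and ILMN_1246790 (6.44 against 5.63). A strictly steady gradient along the chip would place control replicate 3 below its neighbour Chd1 shRNA replicate 1, and it stood 21.8 above it. A looser gradient is not excluded by this. From control replicate 1 to Chd1 shRNA replicate 3 in chip order, the coordinates were -33.1, -26.9, 12.1, -9.70, 22.5 and 35.2. Detected probes in that order numbered 15925, 15663, 15911, 16285, 16816 and 17391. A share of other cells that differed between samples, as in the fibroblast scores, may account for the place of control replicate 3. It was not tested separately from that place.

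With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes past the threshold, which each of the 10 splits must reach, so that count tests nothing, and the highest other count was 529. At an unadjusted p under 0.05 it gave 1268 genes, 2 splits, the real one included, gave at least as many, and the highest other count was 2288. It gave 8 gene lists, 4 splits, the real one included, gave at least as many, and the highest other count was 10. The split with 529 genes set control replicates 1 and 2 and Chd1 shRNA replicate 1 against the other 3 arrays, which points to a structure of the samples other than their groups.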
